A study of Mus musculus with 12 samples.

How the data were processed

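RNA was sequenced from mouse liver in 4 groups of 3 samples. Per the labels, the livers lacked p62 (the protein of Sqstm1) in a liver-specific way. They were either uninfected or taken 7 days after injection of an adenovirus carrying GFP, wild-type p62 or a p62 titled "KIR-". The labels do not spell out KIR. The comparisons were planned with it read as the KEAP1-interacting region, altered in this mutant, which is called the KIR mutant here. The mice had fasted for 15 hours, and total RNA was extracted with a column kit, per the labels' protocols. The groups are called uninfected, Ad-GFP, Ad-p62WT and Ad-p62KIR here, after the sample titles, which also number the samples 1 to 3 in each group. No sample labelled as having intact Sqstm1 was analysed here, so the effect of losing the gene was not measured.

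The authors deposited 1 table of FPKM values (fragments mapped to a gene, relative to its length and to the mapped fragments of the library) per gene and sample, per the file headers. The submitters' processing notes name the genome build mm10 and the tools TopHat, Cufflinks and Cuffdiff; their versions, settings, strand handling and gene annotation are not given in the sources used here. FPKM values are relative to the total of each library and to gene length, so they are not counts, and a gene that takes a larger share of a library lowers all other values in it. The table held 24889 entries, of which 17422 were above 0 in at least 1 sample. Repeated gene names numbered 276, with 542 entries beyond the first of each name, and each entry was kept apart. No 2 samples held identical values, and the correlation of log2 values between samples ran from 0.870 to 0.979. Low values were searched for the whole-number steps that a read count would leave, and at most 3.04% of low genes shared 1 step between samples of a group, so whole reads were not recovered. The sequencing depth of the samples is therefore unknown, and the spread between samples is the measure of precision used here.

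An exact 0 in the table can be a failed estimate. Alb, the most abundant protein product of liver, was listed at 0 in all 12 samples, and 316 of the tested genes were at 0 in at least 1 sample. Genes listed at 0 throughout a group are given as values per sample, without a fold.

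Genes with an FPKM of at least 1 in at least 3 of the 12 samples were tested, which left 11168. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in one fit of the 4 groups (lmFit and eBayes with a trend in the prior variance). The 4 comparisons were drawn from the fit as two-sided tests, and a moderated F test asked for any difference among the groups. Benjamini-Hochberg adjustment was made over the genes tested within each comparison, and genes were called at an adjusted p under 0.05. Each log2 change is on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. Standard errors (SE) are those of the log2 change in limma, and values are means ± SD over the 3 samples of a group. The labels do not state that the samples are separate animals, so p-values measure the spread between the samples as labelled.

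Before the data were examined, 30 gene lists with 745 members were fixed, of which 738 were in the table and 647 were tested. They covered NRF2 targets, growth factor ligands, growth factor receptors, FOXO1 and fasting targets in liver, glycolysis, fatty acid synthesis, cholesterol synthesis, PPARA fatty acid oxidation, bile acid synthesis and transport, cytochrome P450 drug metabolism, hepatocyte secreted proteins, acute phase, interferon response, antigen presentation, markers of T and NK cells, B and plasma cells, macrophages and monocytes, neutrophils, stellate cells and fibrosis, endothelium, and cholangiocytes and progenitors, cell cycle, p53 targets, ER stress and ATF4, heat shock and proteasome, autophagy and lysosome, NF-kB and inflammatory cytokines, sex-biased liver genes, clock genes, and blood and pancreas. The 28 lists with at least 5 tested members were tested with camera (limma) at its preset correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the lists within a comparison. Camera compares a list with all other genes. Each camera test was repeated with a correlation estimated from the residuals of the list, and each list was also tested with fry, which asks whether the members move on balance one way. The level of the NRF2 list in a sample was the mean of its members' log2 values, compared by an exact two-sided permutation test, whose smallest p with 3 samples against 3 is 0.1.

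Named genes followed a rule fixed before the data were examined. It took 10 genes whatever their result (Sqstm1, Nfe2l2, Keap1, Nqo1, Gclc, Gclm, Hmox1, Pdgfa, Pdgfc and Egf). It then took the 8 largest rises and 8 largest falls among called genes whose samples did not overlap between the groups and whose higher mean was at least 2 FPKM, or, where fewer than 5 genes were called in a direction, the 5 with the smallest p, by value. It also took up to 4 members with the smallest p of each list described. Predicted genes were counted and not named, and some genes that met the rule are not reported here. Coordinates and overlaps of genes came from the GENCODE vM21 annotation of GRCm38, matched by symbol.

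The tests were tried on simulated data with 200 changed genes among 11168 before use. At a log2 change of 1, the share of changed genes recovered was 69% for Ad-p62WT against Ad-GFP, 69% for Ad-p62KIR against Ad-GFP, 82% for Ad-p62WT against Ad-p62KIR and 74% for Ad-GFP against uninfected. At a log2 change of 2 it was 96%, 99%, 96% and 96% in the same order, and false calls made up 1.79%, 4.55%, 5.32% and 6.59% of all calls.

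The alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, scaling each sample by its median ratio to the geometric mean sample, quantile normalization, no trend in the prior variance, array weights per sample, the replicate number as a block, the first number of a code in the sample descriptions as a term, only the 6 samples of the groups compared, and each of the 12 samples left out in turn. Alternatives added after the data were seen left out the genes listed at 0 throughout a group, scaled each sample to 112 genes of the proteasome and the mitochondrial ribosome, counted list members without Ad-p62KIR replicate 3, tested 18 gene families grouped by symbol, and took genes of at least 300 bp and under 300 bp of exons apart.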

Results

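RNA sequencing measured gene expression in 12 samples of mouse liver with a liver-specific knockout of p62, per the labels. The protein p62 is an autophagy receptor encoded by Sqstm1 that also binds KEAP1, the adaptor protein that marks the transcription factor NRF2 for degradation. The 4 groups of 3 samples were uninfected, or had received an adenovirus 7 days earlier. It carried GFP (Ad-GFP), wild-type p62 (Ad-p62WT) or the p62 mutant titled "KIR-" (Ad-p62KIR, the KIR mutant). Expression was given as FPKM, so the depth behind each value is unknown. Summed FPKM ran from 377408 to 503086 per sample, and the number of genes with at least 1 FPKM was 8735 to 9243 in uninfected samples and 10238 to 10999 in the others. The first principal component held 61.9% of the variance and placed the uninfected samples between -82.4 and -72.3 and all others between 13.8 and 37.4. The second held 10.6%, with Ad-p62KIR replicate 3 at 53.5 and the other samples between -20.2 and 11.8.

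Sqstm1, the gene knocked out and returned, was read in every sample. Its FPKM was 4.58, 4.62 and 6.74 in uninfected samples, 22.6, 19.3 and 25.4 with Ad-GFP, 59.3, 39.2 and 46.8 with Ad-p62WT, and 39.4, 34.8 and 39.7 with Ad-p62KIR. All 6 samples with a p62 vector lay above all 6 without one. Against Ad-GFP, Sqstm1 rose with wild-type p62 (log2 change 1.06, SE 0.18, limma adjusted p = 0.00853). Without Ad-GFP replicate 2 this rise was 0.97 and missed the threshold (limma adjusted p = 0.0539). The log2 change with the KIR mutant was 0.74 (SE 0.18, limma adjusted p = 0.666). The vectors differed by 0.33 (SE 0.18, limma adjusted p = 0.386). The table gives 1 value per gene, so vector and mouse transcripts are not told apart. The part of the gene that was deleted is not given in the sources used here. The gene lies at chromosome 11, 50199366 to 50210827 on the minus strand (GRCm38), and its exons overlap those of Mrnip on the other strand, so its level carries that uncertainty.

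The comparison of Ad-p62WT with Ad-GFP asked what the wild-type p62 vector changed in livers labelled as p62 knockout, where Sqstm1 was still read; the series title points to NRF2, growth factor genes, AKT and liver enlargement. Targets of NRF2, which drives detoxification and glutathione genes, rose together. Of 44 tested members, 29 rose and 0 fell (limma; at an unadjusted p under 0.05, 40 were higher and 0 lower), and adjusted over the list alone 38 rose. Nqo1, a quinone reductase, went from 12.3 ± 2.62 to 60.1 ± 7.81 FPKM (SD, n = 3), a log2 change of 2.21 (SE 0.18, limma adjusted p = 3.60e-05). Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, went from 63.2 ± 4.24 to 398 ± 38.6 FPKM (log2 change 2.63, SE 0.25, limma adjusted p = 1.13e-04). Its partner Gclm rose less, from 82.7 ± 0.988 to 140 ± 20.7 FPKM (log2 change 0.74, SE 0.17, limma adjusted p = 0.0489).

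Among the largest rises were Cbr3, a carbonyl reductase, at 3.02 ± 2.06 FPKM with Ad-GFP and 194 ± 24.8 with wild-type p62 (log2 change 5.71, SE 0.30), and Gpx2, a glutathione peroxidase, at 0.144 ± 0.0466 and 21.4 ± 4.93 (4.27, SE 0.15). The glutathione transferases Gsta1 (3.99, SE 0.35) and Gstm4 (2.33, SE 0.19), the efflux pump Abcc4 (3.59, SE 0.30) and the cystine transporter Slc7a11 (3.01, SE 0.15) rose too. Cyp2a4 rose by a log2 change of 6.26 (SE 0.80) and Cyp2a5 by 2.56 (SE 0.31); Cyp2a4 and Cyp2a5 are near-identical copies, as are Gsta1 and Gsta2, so the split of reads within each pair is uncertain. Ugt1a6a, whose exons overlap those of other Ugt1a genes, was at 34.7, 34.6 and 37.3 FPKM with wild-type p62 and listed at 0 in all Ad-GFP samples. Mir3113, a short gene inside Huwe1, was at 253, 127 and 152 FPKM with wild-type p62 and listed at 0 in the other 9 samples. Limma adjusted p-values of these genes ran from 1.33e-09 (Mir3113) to 0.00746 (Ugt1a6a).

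NRF2 pathway genes outside this response were Hmox1, heme oxygenase, at 125 ± 16.5 and 107 ± 16.2 FPKM (SD, n = 3; log2 change -0.23, limma adjusted p = 0.639), and Keap1, at 19.6 ± 1.40 and 19.3 ± 1.26 (-0.02, limma adjusted p = 0.974). Nfe2l2, which encodes NRF2 itself, had a log2 change of -0.78 that missed the threshold narrowly (SE 0.18, limma adjusted p = 0.05005) and passed it after median-ratio scaling (limma adjusted p = 0.0420). The mean log2 level of the NRF2 list was 7.22 ± 0.0923 with wild-type p62 and 5.67 ± 0.135 with Ad-GFP (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). By camera the list stood above all other genes (adjusted p = 7.58e-58), and its adjusted p = 0.00185 with an estimated correlation.

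**Figure D1:**
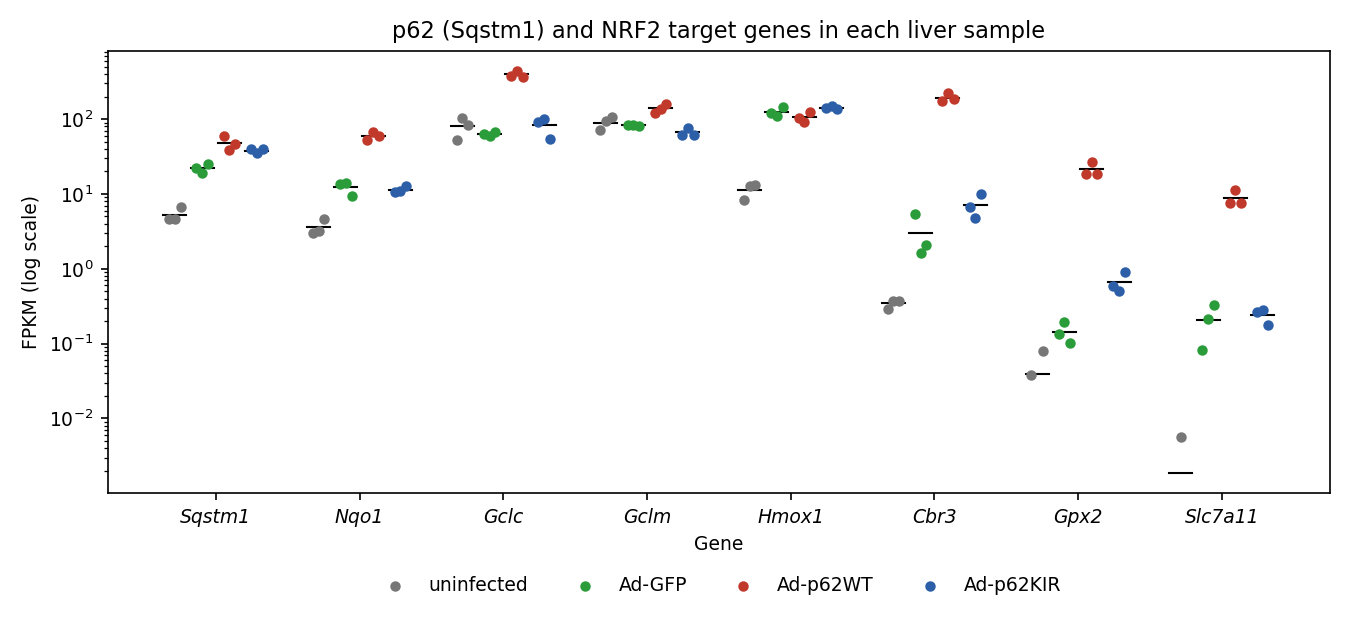
FPKM on a log scale of Sqstm1 and 7 NRF2 target genes in the 12 samples; points are samples, bars are group means, and values of 0, which a log axis cannot show, are left out (Slc7a11 and Gpx2 in some uninfected samples). Nqo1, Gclc, Cbr3, Gpx2 and Slc7a11 lie higher with wild-type p62 than with the KIR mutant, while Hmox1 does not.

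Few growth factor genes, which the study's title names, passed the test in this comparison. Of 25 tested growth factor ligands, 1 rose and 1 fell, and adjusted over the list alone 1 rose and 2 fell. Igf1, the liver's main endocrine growth factor, fell by 0.62 (SE 0.13, limma adjusted p = 0.0371). Pdgfa was at 3.42 ± 0.290 FPKM with Ad-GFP and 1.87 ± 0.333 with wild-type p62 (-0.63, limma adjusted p = 0.137), Pdgfc at 4.17 ± 1.51 and 4.59 ± 0.718 (0.14, limma adjusted p = 0.864), and Egf was between 0.0367 and 0.123 FPKM in all 12 samples and was not tested. Of 20 growth factor receptors, 0 rose and 1 fell, Lifr (-0.89, limma adjusted p = 0.0446); 2 were higher and 5 lower at an unadjusted p under 0.05, and adjusted over the list alone 2 rose and 1 fell. After median-ratio scaling Igf1 and Lifr did not pass (limma adjusted p = 0.0764 and 0.0874). Camera called neither list (adjusted p = 0.805 for ligands, whose median lay below and mean above that of all genes, and 0.321 for receptors). Among 22 FOXO1 and fasting targets in liver, genes that AKT restrains through FOXO1, 0 rose and 1 fell: Fbp1, an enzyme of gluconeogenesis, from 449 ± 96.5 to 221 ± 20.4 FPKM (SD, n = 3), also the only call adjusted over the list alone. Camera placed the FOXO1 list below other genes (adjusted p = 0.0399), with adjusted p = 0.713 with an estimated correlation, and between 0.0730 and 0.171 when Ad-GFP replicate 1 or 2, Ad-p62WT replicate 2 or 3 or Ad-p62KIR replicate 3 was left out.

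Cyp1a1 (log2 change 1.55, SE 0.22), Cyp1a2 (1.47, SE 0.18) and Cyp2a5 rose among 22 tested cytochrome P450 drug metabolism genes and 0 fell, with 5 lower at an unadjusted p under 0.05 in limma; adjusted over the list alone 4 rose and 2 fell. The list's median lay below that of all genes and its mean above, and camera did not call it (adjusted p = 0.830).

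Some plasma protein genes of the liver fell. Of 27 acute phase genes, 5 fell and 0 rose, among them the heme carrier Hpx (log2 change -1.10, SE 0.16) and the endotoxin-binding protein Lbp (-0.75, SE 0.13); 13 were lower and 0 higher at an unadjusted p under 0.05 in limma, and adjusted over the list alone 11 fell. Of 28 hepatocyte secreted proteins, 3 fell, among them transferrin, Trf (-1.09, SE 0.17), and fetuin-A, Ahsg (-1.01, SE 0.18; limma adjusted p = 0.0522 after median-ratio scaling), and 7 adjusted over the list alone. Camera called both lists lower (adjusted p = 1.03e-06 and 1.30e-04), each with adjusted p = 0.626 with an estimated correlation.

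Markers of other cell types moved in both directions. Of 16 endothelial markers, Clec4g (log2 change 0.94, SE 0.19) and Lyve1 (1.45, SE 0.31), both of liver sinusoids, rose, and 5 rose adjusted over the list alone (camera adjusted p = 1.91e-08). Of 26 T and NK cell markers, Cd3d (-0.61, SE 0.11) and Lat (-0.78, SE 0.16) fell, and 5 adjusted over the list alone (camera adjusted p = 3.83e-04). None of 31 cell cycle genes was called in limma, though 15 were higher and 1 lower at an unadjusted p under 0.05 and 3 rose adjusted over the list alone, Rrm2 being at 28.2 ± 4.93 against 11.8 ± 4.53 FPKM (SD, n = 3); camera called the list higher (adjusted p = 4.04e-12). Antigen presentation, with 0 of 21 called by limma, 7 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, was called lower by camera (adjusted p = 0.00136). All 4 calls were lost with an estimated correlation (each adjusted p = 0.626 with an estimated correlation). Of 40 interferon response genes, Mx1 (1.22, SE 0.15) and Oasl1 (1.10, SE 0.23) rose and 6 rose adjusted over the list alone; camera gave adjusted p = 0.00134, 0.0525 without Ad-GFP replicate 1, and adjusted p = 0.713 with an estimated correlation.

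Camera called 5 further lists with less margin. Fatty acid synthesis was called higher (1 of 19 rose, 2 adjusted over the list alone; adjusted p = 0.0332). Called lower were bile acid synthesis and transport (0 of 18 called by limma, 1 higher and 5 lower at an unadjusted p under 0.05, 3 lower adjusted over the list alone; adjusted p = 0.0332), macrophage and monocyte markers (2 of 25 fell, 3 adjusted over the list alone; adjusted p = 0.0332), stellate cell and fibrosis genes (1 of 25 fell, 2 adjusted over the list alone; adjusted p = 0.0209) and NF-kB and inflammatory cytokines (2 of 23 fell, 3 adjusted over the list alone; adjusted p = 0.0217). None held (adjusted p between 0.626 and 0.747 with an estimated correlation), and each lost its call when some single sample was left out, reaching 0.115 to 0.456.

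The largest falls with wild-type p62 included Igfbp2, an insulin-like growth factor binding protein, from 51.4 ± 15.2 to 9.75 ± 3.99 FPKM (SD, n = 3; log2 change -2.33, SE 0.37, limma adjusted p = 0.00504), Marco, a macrophage scavenger receptor (-1.44, SE 0.29), and Jund (-1.38, SE 0.20). Ang (-1.66) and Rnase4 (-1.36) fell as well, but their exons overlap on the same strand, so they are not separate observations. Ddit3, a stress-induced transcription factor, was at 5.51, 4.46 and 6.21 FPKM with Ad-GFP and listed at 0 with wild-type p62. It was also listed at 0 in all uninfected samples, so these values of 0 can be failed estimates. Snord35b, a small nucleolar RNA, was at 98.5, 47.4 and 78.4 and listed at 0 in the other 9 samples.

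In all, 209 of 11168 genes differed between Ad-p62WT and Ad-GFP by limma, 150 higher and 59 lower, of which 98 and 21 by a log2 change above 1. The groups' samples did not overlap in any of the 209, against 29.2% of all tested genes and 10% for chance. A whole group was listed at 0 in 8 of them. Of 28 lists, camera called 14 and 1, the NRF2 list, held with an estimated correlation. The count was 113 without Ad-GFP replicate 2, 111 without Ad-GFP replicate 3, 126, 111 and 133 without Ad-p62WT replicate 1, 2 or 3, and 429 without Ad-p62KIR replicate 3, which enters through the shared spread. It was 2265 with array weights and 411 with the 6 samples alone.

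The comparison of Ad-p62KIR with Ad-GFP asked what the mutant still changed. Only 1 gene of 11168 passed in limma, Snord35b, listed at 0 in all Ad-p62KIR samples, while 801 genes had an unadjusted p under 0.05. Of the NRF2 targets, Nqo1 was at 11.4 ± 1.19 FPKM against 12.3 ± 2.62 (SD, n = 3; log2 change -0.08, limma adjusted p = 0.905), Gclc at 82.3 ± 24.3 against 63.2 ± 4.24 (0.33, limma adjusted p = 0.724) and Gclm at 66.9 ± 8.81 against 82.7 ± 0.988 (-0.31, limma adjusted p = 0.666). Among those with large rises under wild-type p62, Gpx2 was at 0.672 ± 0.213 against 0.144 ± 0.0466 FPKM, without overlap, and Cbr3 at 7.10 ± 2.63 against 3.02 ± 2.06 (SD, n = 3; both limma adjusted p = 0.666). Of the 44 targets 0 were called by limma, 6 were higher and 0 lower at an unadjusted p under 0.05, and 1 rose adjusted over the list alone, Gsta1 at 9.54 ± 2.19 against 3.14 ± 2.98 FPKM. Camera called the list higher (adjusted p = 2.31e-04), with adjusted p = 0.511 with an estimated correlation and 0.0580 without Ad-p62KIR replicate 3. The list's mean log2 level was 5.85 ± 0.0851 against 5.67 ± 0.135 (SD, n = 3; exact permutation p = 0.3). Hmox1 (log2 change 0.19, limma adjusted p = 0.767), Nfe2l2 (-0.48, limma adjusted p = 0.666), Keap1 (0.03, limma adjusted p = 0.953), Pdgfa (-0.18, limma adjusted p = 0.786) and Pdgfc (-0.19, limma adjusted p = 0.818) did not pass.

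The smallest p-values of higher genes with the mutant were mostly of interferon genes. Isg15, an interferon-induced ubiquitin-like protein, was at 63.5 ± 9.53 FPKM against 32.6 ± 4.30 (SD, n = 3; log2 change 0.94, limma adjusted p = 0.123), Irf7 at 128 ± 7.86 against 72.3 ± 13.2 (0.83, limma adjusted p = 0.231) and Oas1a at 8.77 ± 0.635 against 4.85 ± 0.630 (0.74, limma adjusted p = 0.257). Of the 40 interferon response genes 0 were called by limma, 13 were higher and 0 lower at an unadjusted p under 0.05, and 4 rose adjusted over the list alone. Of 8 neutrophil markers 0 were called by limma, 5 were higher at an unadjusted p under 0.05, and the same number rose adjusted over the list alone, among them S100a9 (log2 change 1.33, SE 0.37, limma adjusted p = 0.666). Camera called both lists (adjusted p = 1.88e-10 and 1.71e-07), and neither held (each adjusted p = 0.511 with an estimated correlation). Small p-values were also those of Ifit3b (0.54) and the chemokine Ccl7 (1.01), each at a limma adjusted p = 0.468. Those of lower genes, besides Snord35b, were of Pfn2 (-0.86, limma adjusted p = 0.118), Arrdc3 (-0.69) and Bmi1 (-0.61, both limma adjusted p = 0.666), and Snora21, at 5.58, 5.92 and 5.09 FPKM with Ad-GFP and listed at 0 with the mutant. Antigen presentation had 0 of 21 genes called by limma, 5 higher and 0 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone; camera called it higher (adjusted p = 6.28e-06), but adjusted p = 0.511 with an estimated correlation. Camera called 17 of 28 lists and 0 of them held with an estimated correlation (adjusted p between 0.511 and 0.726); fry called 0. Besides the interferon, neutrophil and antigen presentation lists, all 14 called lists lost the call when some single sample was left out.

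The comparison of Ad-p62WT with Ad-p62KIR tested the difference between the p62 vectors itself, at Sqstm1 levels whose difference did not pass. NRF2 targets again set them apart: 27 of 44 were higher with wild-type p62 and 0 lower (limma; 35 higher and 1 lower at an unadjusted p under 0.05), and adjusted over the list alone 35 were higher and 1 lower. Nqo1 differed by a log2 change of 2.29 (SE 0.18, limma adjusted p = 3.39e-05), Gclc by 2.30 (SE 0.25, limma adjusted p = 4.73e-04), Gclm by 1.05 (SE 0.17, limma adjusted p = 0.00643), Gpx2 by 3.73 (SE 0.15), Cbr3 by 4.63 (SE 0.30), Abcc4 by 3.59 (SE 0.30) and Slc7a11 by 2.97 (SE 0.15). Camera gave the list an adjusted p = 3.80e-39, and its adjusted p = 0.00734 with an estimated correlation. Hmox1 (log2 change -0.42, limma adjusted p = 0.279), Nfe2l2 (-0.30, limma adjusted p = 0.413), Keap1 (-0.05, limma adjusted p = 0.858), Pdgfa (-0.45, limma adjusted p = 0.263) and Pdgfc (0.34, limma adjusted p = 0.484) did not pass. Other large differences were Cyp2a4 (4.68, SE 0.80) and Ugt1a6a, which was listed at 0 in Ad-p62KIR replicates 1 and 3 and at 19.9 FPKM in replicate 2 (limma adjusted p = 0.0488, and 0.0525 after median-ratio scaling). Htra2, which overlaps Aup1 and Loxl3 on the other strand, was at 10.6, 12.3 and 10.9 FPKM with wild-type p62 and listed at 0 with the mutant. It was at 0, 0 and 15.8 FPKM with Ad-GFP and at 0 in uninfected samples, so its values of 0 can be failed estimates.

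Some immune and plasma protein genes were lower with wild-type p62 than with the mutant, while Mx1 was higher (log2 change 0.94, SE 0.15, limma adjusted p = 0.00538). Of 21 antigen presentation genes 4 were lower, all of class I, such as H2-K1 at 796 ± 60.2 against 1447 ± 286 FPKM (SD, n = 3), and 14 adjusted over the list alone. Of 26 T and NK cell markers 3 were lower, led by Cd3d (log2 change -0.84, SE 0.11), and 9 adjusted over the list alone. Of 23 NF-kB and inflammatory cytokine genes 3 were lower, among them Nfkb2 (-0.74, SE 0.13) and Relb (-0.78, SE 0.15), and 10 adjusted over the list alone. Of 8 neutrophil markers 3 were lower, S100a9 (-1.66), Ngp (-1.99) and Retnlg (-1.54), and 5 adjusted over the list alone. Of 27 acute phase genes 3 were lower, with Hpx at -0.91 (SE 0.16), and 12 adjusted over the list alone; of 28 hepatocyte secreted proteins 3 were lower, with Ahsg at -1.05 (SE 0.18), and 11 adjusted over the list alone. Camera called these 6 lists, with adjusted p from 3.87e-11 to 7.86e-06, and none held (adjusted p between 0.175 and 0.270 with an estimated correlation); fry, which does not compare a list with other genes, called all 6 (adjusted p between 0.0102 and 0.0343). After median-ratio scaling S100a9 and Retnlg did not pass (limma adjusted p = 0.0528 and 0.0543).

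Camera called 4 more lists. Macrophage and monocyte markers were lower (0 of 25 called by limma, 5 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; adjusted p = 2.24e-04, and adjusted p = 0.633 with an estimated correlation). Stellate cell and fibrosis genes were lower (0 of 25 called by limma, 5 lower at an unadjusted p under 0.05, 2 adjusted over the list alone; adjusted p = 0.00542). Endothelial markers (0 of 16 called by limma, 1 higher at an unadjusted p under 0.05, 1 adjusted over the list alone; adjusted p = 0.0175) and cell cycle genes (0 of 31, 1 and 0; adjusted p = 0.00244) were higher. Those 3 each had adjusted p = 0.818 with an estimated correlation and lost the call when some single sample was left out, reaching 0.103, 0.287 and 0.388.

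Igfbp2 (log2 change -2.16, SE 0.37), the organic anion transporter Slco1a1 (-1.71, SE 0.39; limma adjusted p = 0.0570 after median-ratio scaling) and the methyltransferase Inmt (-1.50, SE 0.28) were also lower with wild-type p62. Ddit3 was at 6.33, 4.01 and 18.9 FPKM with the mutant and listed at 0 with wild-type p62 and in uninfected samples, where the values of 0 can be failed estimates. By limma 227 of 11168 genes differed, 151 higher and 76 lower with wild-type p62, of which 96 and 19 by a log2 change above 1. The samples did not overlap in any of the 227, against 20.5% of all tested genes, and 1826 genes had an unadjusted p under 0.05. Of 28 lists camera called 11, and 1 held with an estimated correlation. The count was 129, 110 and 113 without Ad-p62WT replicate 1, 2 or 3, 142 and 383 without Ad-p62KIR replicate 1 or 2, 366 with array weights, 90 with the 6 samples alone and 144 at a mean FPKM of at least 5. Scaled to proteasome and mitochondrial ribosome genes it was 137, of which 83.2% were higher, against 66.5%. Those reference genes were themselves lower with wild-type p62, by a median log2 change of -0.19 for the proteasome and -0.096 for the mitochondrial ribosome. Scaling to them therefore moves the other changes upward.

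**Figure D2:**
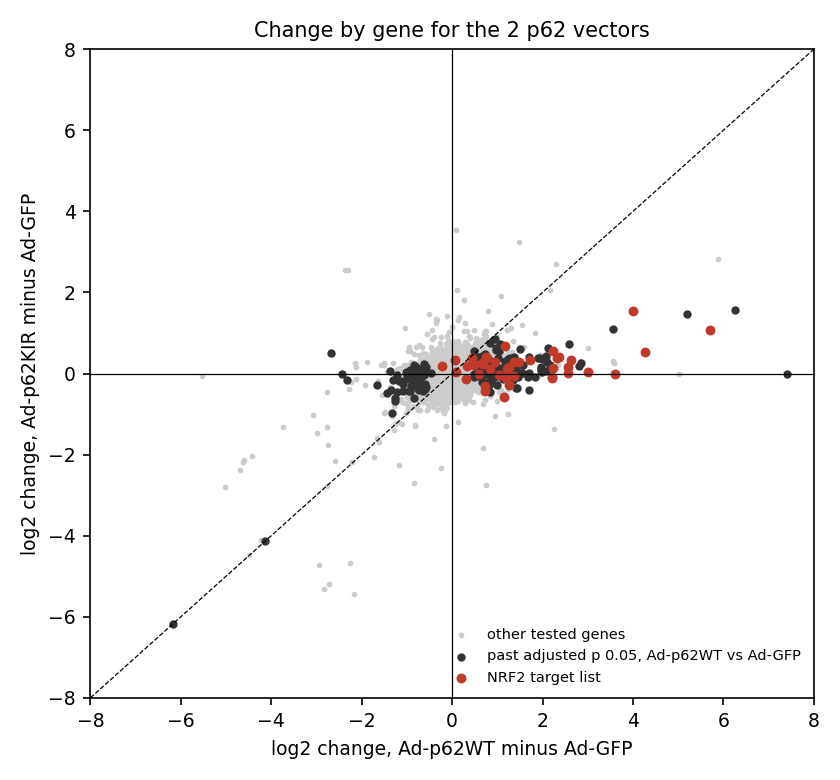
Log2 change against Ad-GFP of each tested gene with wild-type p62 (horizontal axis) and with the KIR mutant (vertical axis); NRF2 list members are red and genes called between Ad-p62WT and Ad-GFP are black. The 150 genes called higher had a median log2 change of 1.22 with wild-type p62 and 0.11 with the mutant.

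The effects of both vectors share the Ad-GFP samples, which alone gives them a correlation. Over all 11168 genes the log2 changes correlated at r = 0.40 (genes are not independent replicates), against 0.50 (0.38 to 0.61) in simulations of unchanged groups, with a covariance of 0.0522 against 0.0413 simulated. Over the 209 called genes, which were selected for a large change with wild-type p62, r was 0.61 and the covariance was 0.590. Simulations of unchanged groups gave an r of 0.487 on average (0.232 to 0.764) and a covariance of 0.0273. They held no effect of either vector and did not repeat the selection. They therefore cannot tell how much of this r comes from the shared Ad-GFP samples. Of the 150 higher and 59 lower genes with wild-type p62, 118 and 31 were also called between wild-type p62 and the mutant in the same direction, where independent lists would share 2.03 and 0.402. That overlap shares the Ad-p62WT samples, so independent lists are a low bar, and 3 control samples are too few to split.

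The comparison of Ad-GFP with uninfected livers measured the vector control against no vector. In it 6623 genes differed by limma, 6130 higher and 493 lower (92.6% higher), and the median log2 change of all tested genes was 0.49. Scaled by median ratios, 4737 differed, 2569 higher and 2168 lower (54.2% higher); by quantile normalization 41.8% of 4526 were higher with a median of -0.13, and scaled to proteasome and mitochondrial ribosome genes 82.6% of 4334 were higher with a median of 0.32. Changes are therefore given as deposited and then, as "scaled", after median-ratio scaling, which sets the median of all genes to 0.

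Immune genes rose far above this shift. All 40 interferon response genes rose, as deposited and scaled, and likewise adjusted over the list alone; the chemokine Cxcl10 changed by 4.65 (scaled 4.16) and Cxcl9 by 4.73 (scaled 4.18), from 3.41 ± 0.853 to 114 ± 2.77 FPKM (SD, n = 3). All 21 antigen presentation genes rose (20 scaled; 21 adjusted over the list alone), with the class II chain H2-Aa from 32.0 ± 7.62 to 874 ± 203 FPKM. Of 26 T and NK cell markers 25 rose (25 scaled; 25 adjusted over the list alone), with Cd8b1 at 2.88 (scaled 2.65) and the chemokine Ccl5 at 5.27 (scaled 4.73). Of 25 macrophage and monocyte markers 22 rose and 1 fell (22 and 1 scaled, and adjusted over the list alone), with the complement gene C1qb at 3.56 (scaled 2.94). Of 23 NF-kB and inflammatory cytokine genes 22 rose and 0 fell (20 and 1 scaled; 22 and 0 adjusted over the list alone), with Ccl4 at 4.30 (scaled 4.01). Camera called all 5 lists higher (adjusted p from 2.53e-13 to 1.89e-08), but adjusted p = 0.0814 with an estimated correlation for 4 of them and 0.148 for macrophages and monocytes. Of 8 neutrophil markers 5 rose (5 scaled; 5 adjusted over the list alone), S100a8 at 4.16 (scaled 3.85), and camera did not call the list (adjusted p = 0.144). Of 3 tested B and plasma cell markers, too few to test as a list, 3 rose, with Jchain at 2.00 (scaled 1.51). Of 3 tested blood and pancreas genes Hba-a1 rose (1.08, scaled 0.46 and not called) and Alas2, of heme synthesis in red cells, fell (-1.20, scaled -1.83); in the other comparisons 0 genes of these 2 lists were called.

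Proliferation, damage response and matrix genes rose too. All 31 cell cycle genes rose (31 scaled, and 31 adjusted over the list alone), with the replication helicase subunit Mcm6 at 3.58 (scaled 3.19). Among them Ccna2, Ccne2, Cdc20 and Kif20a were listed at 0 in all uninfected samples, and Cdc20 also in Ad-GFP replicate 2. Their exons overlap those of other genes, so these values of 0 can be failed estimates. Of 20 p53 targets 17 rose (14 scaled; 18 adjusted over the list alone), with Phlda3 at 3.20 (scaled 2.86) and Bax at 1.67 (scaled 1.05). Of 25 stellate cell and fibrosis genes 24 rose (21 scaled; 24 adjusted over the list alone), with vimentin, Vim, at 3.28 (scaled 2.70) and Timp1 at 2.90 (scaled 2.67). Camera called these 3 lists higher (adjusted p = 4.31e-06, 4.78e-04 and 3.11e-05); none held (adjusted p = 0.485, 0.396 and 0.330 with an estimated correlation). Of 12 cholangiocyte and progenitor markers 7 rose (3 scaled; 7 adjusted over the list alone), with Afp at 1.08 (scaled 0.85; camera adjusted p = 0.566). Of 16 endothelial markers 5 rose and 1 fell, but 0 rose and 5 fell scaled and 4 rose adjusted over the list alone (camera adjusted p = 0.0559).

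Hepatocyte functions lay below the shift. Of 28 hepatocyte secreted proteins 1 rose and 10 fell (0 and 25 scaled; 0 and 10 adjusted over the list alone), with apolipoprotein Apoa2 at -1.77 (scaled -2.41). Of 18 bile acid synthesis and transport genes 0 rose and 8 fell (0 and 14 scaled; 7 fell adjusted over the list alone), with the bile acid ligase Slc27a5 at -1.49 (scaled -2.13) and Cyp7b1 at -2.02 (scaled -2.65). Of 26 genes of PPARA fatty acid oxidation 1 rose and 8 fell (0 and 17 scaled; 1 and 7 adjusted over the list alone). Of 22 cytochrome P450 drug metabolism genes 3 rose and 9 fell (1 and 12 scaled; 3 and 9 adjusted over the list alone), with Cyp2f2 at -1.61 (scaled -2.25) and Cyp3a11 at 0.95 (scaled 0.31 and not called). Of 22 FOXO1 and fasting targets 2 rose and 7 fell (0 and 11 scaled; 2 and 6 adjusted over the list alone), with G6pc, of glucose release, at -1.26 (scaled -1.89). Of 13 sex-biased liver genes 2 rose and 6 fell (0 and 7 scaled; 2 and 6 adjusted over the list alone), with Hsd3b5 at -4.40 (scaled -4.93). Camera called these 6 lists lower (adjusted p from 9.61e-15 to 1.99e-06), each with adjusted p = 0.0814 with an estimated correlation.

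Of 22 cholesterol synthesis genes 1 rose and 9 fell (0 and 13 scaled; 1 and 8 adjusted over the list alone), with Fdps at -1.45 (scaled -2.07), and of 19 fatty acid synthesis genes 2 rose and 3 fell (1 and 8 scaled; 2 and 3 adjusted over the list alone), with the desaturase Fads1 at -0.83 (scaled -1.46). Of 16 clock genes 3 rose and 2 fell (0 and 5 scaled; 2 and 2 adjusted over the list alone), with Nfil3 at -1.27 (scaled -1.87), and of 24 heat shock and proteasome genes 2 rose and 0 fell (0 and 7 scaled; 1 rose adjusted over the list alone), with Psma1 at 0.62 (scaled -0.01). Camera called these 4 lists lower relative to other genes (adjusted p = 3.78e-11, 7.29e-06, 0.00250 and 0.0183), and none held (adjusted p between 0.0814 and 0.564 with an estimated correlation); the heat shock and proteasome list was also lost without uninfected replicate 1 (0.0896) or Ad-p62KIR replicate 3 (0.0548).

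The remaining lists were not called by camera. NRF2 targets counted 16 higher and 3 lower of 44 (9 and 11 scaled, 16 and 3 adjusted over the list alone, camera adjusted p = 0.184). Hmox1 rose from 11.4 ± 2.72 to 125 ± 16.5 FPKM (SD, n = 3, log2 change 3.36, scaled 2.76) and Nqo1 rose by 1.52 (scaled 0.98). Gclc (-0.29, scaled -0.92) and Gclm (-0.10, scaled -0.73) did not pass as deposited. After scaling both were called lower (limma adjusted p = 0.00822 and 0.00326). Sqstm1 rose by 1.90 as deposited (limma adjusted p = 4.57e-06) and by 1.33 scaled (limma adjusted p = 1.27e-04). Nfe2l2 rose by 1.85 (scaled 1.24), and Keap1 rose by 0.49 as deposited but stood at -0.11 scaled. Among 25 growth factor ligands 12 rose and 3 fell (4 and 9 scaled; 12 and 3 adjusted over the list alone; adjusted p = 0.167), Tgfb1 by 2.64 (scaled 2.23), Pdgfa by 0.87 (scaled 0.45) and Pdgfc by 0.96 (scaled 0.51), neither called after scaling. Among 20 growth factor receptors 6 rose and 3 fell (6 and 6 scaled; 6 and 3 adjusted over the list alone; adjusted p = 0.0568), Axl by 2.97 (scaled 2.51). Among 18 glycolysis genes 12 rose and 1 fell (7 and 1 scaled; 12 and 1 adjusted over the list alone; adjusted p = 0.262), the pyruvate kinase Pkm by 3.40 (scaled 2.92), and Pfkp was listed at 0 in uninfected samples. Among 26 autophagy and lysosome genes 12 rose and 1 fell (2 and 11 scaled; 10 and 1 adjusted over the list alone; adjusted p = 0.201), the lysosomal protease Ctsb by 1.77 (scaled 1.14). Among 24 ER stress and ATF4 genes 9 rose and 1 fell (5 and 2 scaled; 9 and 1 adjusted over the list alone; adjusted p = 0.566), Atf3 by 2.15 (scaled 1.89). Among 27 acute phase genes 15 rose and 3 fell (8 and 7 scaled; 15 and 3 adjusted over the list alone; adjusted p = 0.754), Lcn2 from 27.3 ± 7.17 to 1313 ± 304 FPKM and Serpina3k by -1.99 (scaled -2.63). Camera's direction for the ligand and acute phase lists was lower although their medians and means lay above the median of all genes; for the NRF2 and ER stress lists it was lower, with the median below and the mean above.

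**Figure D3:**
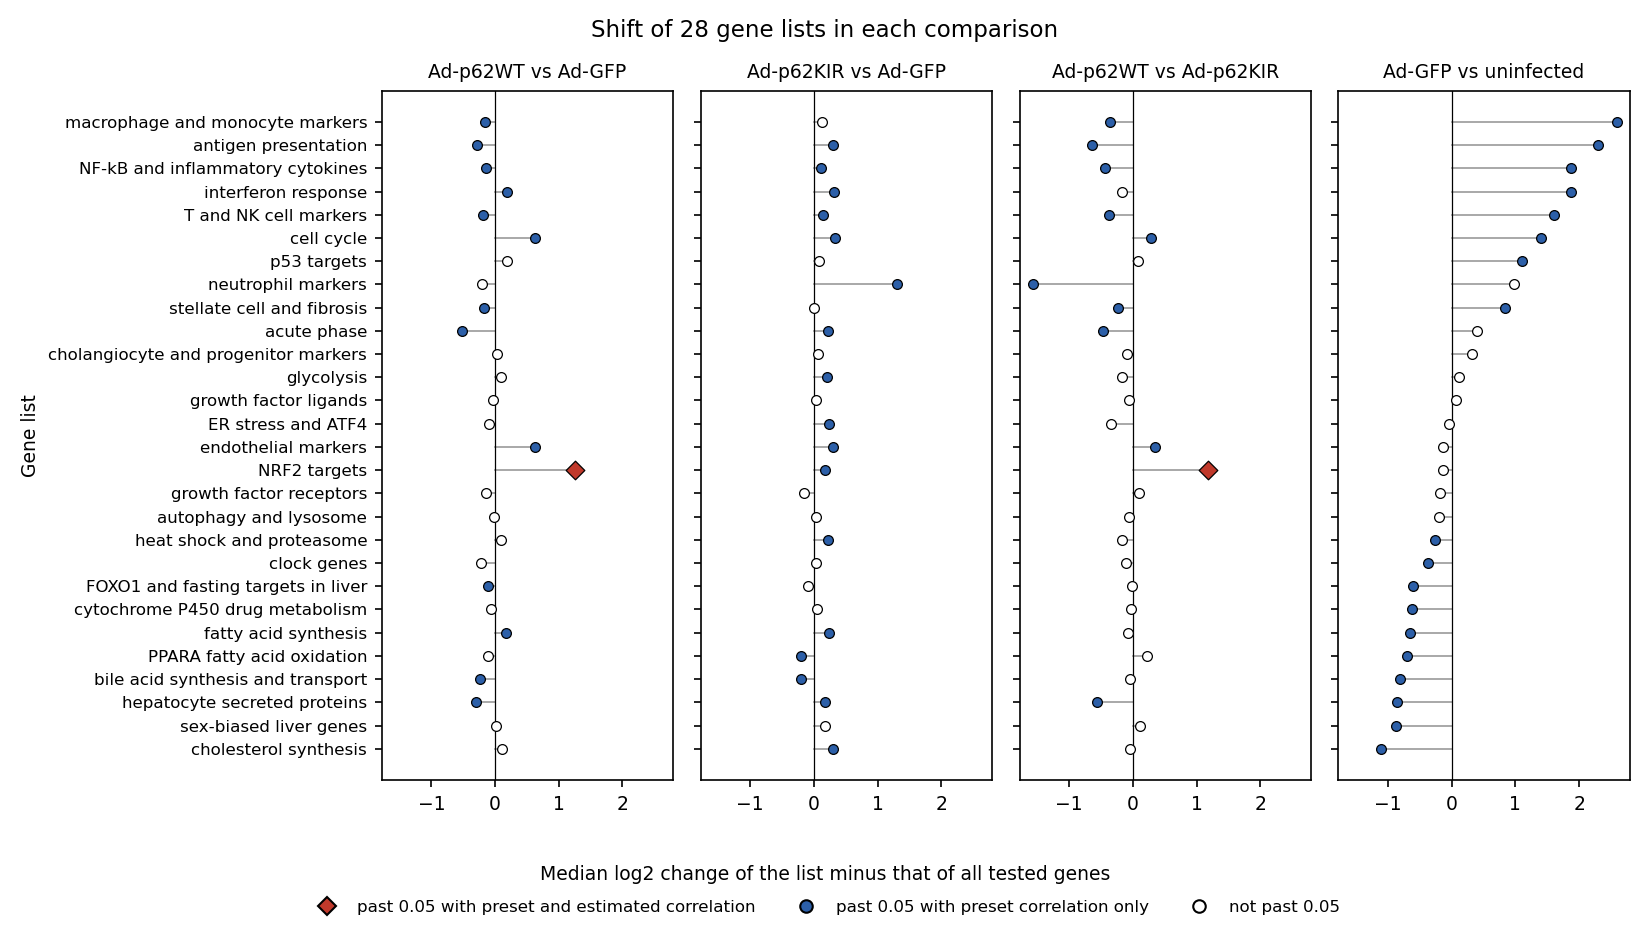
Median log2 change of each of 28 gene lists minus the median of all tested genes, in the 4 comparisons; diamonds mark lists past an adjusted p of 0.05 in camera with both the preset and an estimated correlation. Only NRF2 targets carry diamonds, in Ad-p62WT against Ad-GFP and against Ad-p62KIR; interferon and macrophage lists lie above, and most hepatocyte lists below, all genes in Ad-GFP against uninfected.

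The largest single rises with Ad-GFP included Ubd, an interferon-induced ubiquitin-like protein, from 0.938 ± 0.232 to 94.7 ± 13.5 FPKM (SD, n = 3; log2 change 5.62, SE 0.32), Lcn2 at 5.54 (SE 0.28, scaled 4.92) and Ly6d at 5.42 (SE 0.64). The short RNAs Snord89 (59.4, 104 and 86.4 FPKM), Snora68 (70.9, 49.6 and 127), Snord35b and Snora65 (48.1, 47.0 and 25.8), the last inside Rpl12, were listed at 0 in all uninfected samples. The largest falls included Ces3b, a carboxylesterase, from 117 ± 23.6 to 7.14 ± 4.76 FPKM (SD, n = 3; log2 change -4.07, SE 0.46, scaled -4.66) and Igfbp2 (-2.57, SE 0.37, scaled -3.21). The urinary proteins Mup21 (-2.78, scaled -3.39) and Mup3 (-2.54, scaled -3.18) fell too, in a family of near-identical copies, so their separate levels are uncertain. Surf1, which overlaps Surf2 on the other strand, was at 35.0, 31.3 and 32.2 FPKM in uninfected samples and listed at 0 in the other 9. Dpm1 was at 9.21, 8.86 and 5.23 and listed at 0 with Ad-GFP, and Toporsos was at 67.8, 57.2 and 78.4 and listed at 0 in Ad-GFP replicates 1 and 2, but at 50.2 FPKM in replicate 3, so its fall rests on 2 values of 0. Among the called genes 54 were listed at 0 in a whole group.

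Across the 4 groups together, 6585 of 11168 genes differed by limma's F test. Nqo1 lies at chromosome 8, 107388225 to 107403206 on the minus strand, Gclc at chromosome 9, 77754535 to 77794485 on the plus strand (GRCm38). Gclm lies at chromosome 3, 122245557 to 122270732 on the plus strand, where its exons overlap a predicted gene. Nfe2l2 lies at chromosome 2, 75675513 to 75704641 and Keap1 at chromosome 9, 21229730 to 21239361, both on the minus strand (GRCm38).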

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

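The settings that left out the genes listed at 0, scaled to proteasome and mitochondrial ribosome genes or counted list members without Ad-p62KIR replicate 3 were chosen after the results were seen. Counts of genes past an adjusted p of 0.05 stayed within 1.5 times the value in the report except as follows (limma with Benjamini-Hochberg adjustment). Array weights gave 2265 genes for Ad-p62WT against Ad-GFP (49.5% higher, against 71.8%), 7 for Ad-p62KIR against Ad-GFP and 366 for Ad-p62WT against Ad-p62KIR. A fit of only the 6 samples compared gave 411, 3 and 90 in that order; the cause was not tested. A mean FPKM of at least 5, which tests fewer genes, gave 144 for Ad-p62WT against Ad-p62KIR, 3499 for Ad-GFP against uninfected and 3622 for the F test. Scaling to proteasome and mitochondrial ribosome genes gave 137, 4334 and 3922. For Ad-p62KIR against Ad-GFP, a pseudocount of 5 gave 2 genes, no filter 4, and leaving out genes listed at 0 gave 0 in limma, where as deposited 801 had an unadjusted p under 0.05. After median-ratio scaling 80.5% of the genes called between Ad-p62WT and Ad-GFP were higher, against 71.8%.

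Leaving out single samples gave 111 to 429 genes for Ad-p62WT against Ad-GFP, 1 to 2 for Ad-p62KIR against Ad-GFP (2 without uninfected replicate 3, Ad-GFP replicate 1 or Ad-p62WT replicate 1) and 110 to 383 for Ad-p62WT against Ad-p62KIR. The samples that moved the first and last beyond 1.5 times are named beside those counts in the report. The range was 5455 to 7659 for Ad-GFP against uninfected and 5154 to 7730 for the F test. The Sqstm1 log2 change of Ad-p62WT against Ad-GFP ranged from 0.91 to 1.20, and without Ad-GFP replicate 2 it was 0.97 (limma adjusted p = 0.0539). The NRF2 list kept its call in Ad-p62WT against Ad-GFP and against Ad-p62KIR under all settings tried for lists. In Ad-p62KIR against Ad-GFP its adjusted p was 0.511 with an estimated correlation, 0.489 by fry, and 3.24e-05 to 0.0580 with single samples left out, the last without Ad-p62KIR replicate 3. In Ad-GFP against uninfected it was 8.90e-04 by fry, which does not compare the list with other genes, and quantile normalization turned camera's direction from lower to higher (adjusted p = 0.0381), as it did for the acute phase list (adjusted p = 6.40e-05).

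In Ad-p62KIR against Ad-GFP, 4 list directions turned when a sample was left out. Cholesterol synthesis turned without Ad-GFP replicate 1 (adjusted p = 0.524; range 4.17e-04 to 0.934), as did acute phase (0.571; 1.90e-04 to 0.571) and hepatocyte secreted proteins (0.584; 9.32e-05 to 0.838, the last turned too, without Ad-p62KIR replicate 3). Heat shock and proteasome turned without Ad-p62KIR replicate 3 (0.585; 1.25e-06 to 0.585). For Keap1, Ad-GFP vs uninfected, the log2 change turned with median-ratio scaling (-0.11) and quantile normalization (-0.00610), and so did that of Psma1 with median-ratio scaling (-0.0133). The correlation of both vectors' effects was 0.61 over the called genes, against 0.40 over all. The range simulated for the called genes (0.232 to 0.764) came from unchanged groups without the selection, so it cannot judge the 0.61. Of the called genes named in the text, 19 of 35 kept the call under all settings for Ad-p62WT against Ad-GFP, 8 of 24 for Ad-p62WT against Ad-p62KIR and 51 of 60 for Ad-GFP against uninfected.

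The replicate number as a block gave 190, 1, 204 and 6565 genes in the order of the report and 6429 for the F test. No list call was lost with the block in camera, and the PPARA list passed in Ad-p62WT against Ad-p62KIR (adjusted p = 0.0413). The blocked NRF2 list had adjusted p = 0.591 by fry in Ad-p62KIR against Ad-GFP and 0.00276 in Ad-GFP against uninfected. Only 7 of 18 pairs of same-numbered samples had deviations correlated above 0.1 (-0.25 to 0.29), and 1 of 12 samples correlated best with its own number in all 3 other groups. For 7 of 12 the single highest correlation was with a sample of the same number. Since not all pairs were above 0.1, the numbers were not taken to pair the samples. Tests on read counts were not run, as the values are FPKM. Depth is unknown, so low values cannot be weighed by their counts.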

Other observations

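The gene families, the splits of the samples, the tests of the shift between Ad-GFP and uninfected samples, the tests of short and longer genes apart and both tests of the label of Ad-p62KIR replicate 3 were chosen after the results were seen. The tests of too few fragments, of exon overlap and of transcript length were set before their results were seen.

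Some detoxification families of the hepatocyte were lower with Ad-GFP than in uninfected livers, relative to other genes. Grouped by symbol, camera called 14 of 18 families and 5 held with an estimated correlation. In Ad-p62WT against Ad-GFP, Ad-p62KIR against Ad-GFP and Ad-p62WT against Ad-p62KIR it called 10, 10 and 6, and 0 held. Glutathione transferases in Ad-p62WT against Ad-GFP (8 rose and 0 fell of 22 in limma) had a camera adjusted p = 0.0724 with an estimated correlation. Of the 12 transferases outside the NRF2 list 2 rose, so most of these rises repeat that list. In Ad-GFP against uninfected, glutathione transferases (5 rose and 4 fell of 22, 2 and 11 scaled by median ratios; adjusted p = 0.289), aldo-keto reductases (5 and 4 of 13, 3 and 6 scaled; adjusted p = 0.353) and aldehyde dehydrogenases (6 and 3 of 15, 2 and 8 scaled; adjusted p = 0.0843) did not hold. Of 12 carboxylesterases, which cleave esters of drugs and lipids, 2 rose and 10 fell in limma (0 and 10 scaled; adjusted p = 0.0292). Of 14 UDP-glucuronosyltransferases 2 rose and 7 fell (0 and 10 scaled; adjusted p = 0.0292), with Ugt2b1 from 354 ± 58.8 to 84.3 ± 19.1 FPKM (SD, n = 3). Of 34 members of cytochrome P450 family 2, 6 rose and 15 fell (2 and 21 scaled; adjusted p = 0.0326). Family 4 had 3 rising and 6 falling of 14 (2 and 9 scaled; adjusted p = 0.00992), with Cyp4f18 at 2.80 and Cyp4f13 at -1.12. Of 7 sulfotransferases 1 rose and 2 fell (1 and 4 scaled; adjusted p = 0.0410), Sult1e1 by 1.29 and Sult2a8 by -2.54. Members of these families share sequence, so single members are uncertain.

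Some genes were listed at 0 in all 3 samples of a group while another group had a mean of at least 5 FPKM. There were 66 of them, and 80 more were at 0 in only 1 or 2 samples of a group, which is consistent with estimates failing sample by sample. Among genes of at least 300 bp of exons the numbers were 32 and 48; under 300 bp they were 30 and 28, where failing estimates and absent transcripts cannot be told apart because the counts are close. Exons of 40 of 62 such genes (64.5%) overlapped another gene, against 36.6% of other tested genes (Fisher exact p = 1.41e-05), and their median exonic length was 978.5 against 4313 bp, so part of these zeros may come from how overlapping or short genes were estimated. A true loss of transcripts in single groups stays open and was not tested.

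Most genes were higher with Ad-GFP than in uninfected samples, by a median log2 change of 0.49. Leaving out the 10 genes with the highest FPKM in uninfected samples kept most of this shift. Without them, and with each sample set to the same summed FPKM, the median change was 0.40. Summed FPKM weighs short genes more than their share of fragments, so this cannot tell what these genes took of the libraries. Other abundant genes were not left out, and Alb, listed at 0, could not be. A larger share of abundant genes in the uninfected libraries therefore stays open. A lower share of hepatocytes that raised all other cell types alike would give similar rises of their markers. The median level rose by 2.62 for macrophages and monocytes, 2.11 for T and NK cells, 1.88 for stellate cells and 0.61 for endothelium. The highest and lowest lay 2.00 apart, with a spread of 0.19, which argues only against an equal rise. The filter may add to the shift, since it could be met by infected samples alone. How much it adds was not tested. A lower share of hepatocytes with unequal gains of other cell types, the authors' normalization and the infection itself also stay open, untested.

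Ad-p62KIR replicate 3 stood apart from its group, at 53.5 on the second principal component. Its deviation from the group correlated with exonic length (Spearman -0.54, the largest of the 12 samples), which is consistent with recovery that depends on transcript length; its group's other samples, measured against means that contain it, had 0.50 and 0.38. Its profile correlated better with Ad-GFP than with its own group (difference -0.0082), but the other samples of the group did so as well (-0.00679 and -0.00815), so by this measure a sample of another group cannot be told apart from a group close to Ad-GFP. Against a label from another group, its Sqstm1 FPKM lay 5.64 SD above Ad-GFP and 27.7 SD above uninfected, and its NRF2 list level 13.8 SD below Ad-p62WT. A sample from outside the series stays open, and no biological explanation was tested.

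The samples of each comparison were also split in other ways. For 3 samples against 3 there are 10 splits, too few for a share under 0.05, and 1, 4, 1 and 1 of them gave as many genes as the real split, itself included, in the order of the report. The real split gave 209 genes against at most 3 in others for Ad-p62WT against Ad-GFP, 227 against 1 for Ad-p62WT against Ad-p62KIR, and 6623 against 1 for Ad-GFP against uninfected. For Ad-p62KIR against Ad-GFP it gave 1 and another split 271, which points to a structure of the samples other than the groups. That split sets Ad-GFP replicate 1 and Ad-p62KIR replicates 1 and 2, with 14 as the number after the sample name in the code of the sample descriptions, against the samples with 16 or 18. The labels do not explain the code. The split also follows the correlation of each sample's deviation with exonic length. That correlation was 0.12, 0.50 and 0.38 for Ad-GFP replicate 1 and Ad-p62KIR replicates 1 and 2. It was -0.02 and -0.16 for Ad-GFP replicates 2 and 3, and -0.54 for Ad-p62KIR replicate 3. Each deviation is measured against the rest of its group, so these values are not independent. Code and length go together in this split, which cannot tell them apart. With this number as a term the real groups still gave 1 gene, and the same division of the Ad-p62WT and Ad-GFP samples gave 2. For the F test, 1 of 100 splits, the real one, reached 6585 genes, and the highest other reached 5485. A share of 1 in 100 is under 0.05 and argues against a random grouping, without excluding it. The count does not say which of the 4 groups differ, and the uninfected samples stood apart from all others on the first principal component.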
